A study of Arabidopsis thaliana with 12 samples.

How the data were processed

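Total RNA of dark-adapted Arabidopsis thaliana plants of the Landsberg ecotype was measured on 12 single-colour arrays, 6 of WT and 6 of the laf6 mutant, as the labels group them. Replicate numbers 1 to 6 were taken from the titles. The deposited values are intensities on a linear scale, with 1 value per feature and array for 3439 features. The scanner, the background correction and any scaling applied by the authors are not given in the sources used here. On every array the deposited intensities ran from exactly 0 to within 0.001 of 100, with 1 to 4 features of an array at that top value. Whether the values were scaled to the brightest features or stopped at a ceiling is not given in the sources used here, so they are treated as having no absolute unit. Across arrays, 15.7% of the intensities were listed at 0, which leaves open how far below the other signals those features lay. The table had no detection calls, and the number of arrays limits the precision, as does the closeness of dim features to the floor described below.

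The main settings, the alternatives, the tests and the preset gene lists were fixed before the data were examined. Array medians were to be left as deposited if they lay within 10% of each other. The highest median was 1.62 times the lowest, so quantile normalization between arrays was used. Because more than 5% of the values were 0, values were then raised to a floor at the 1st percentile of the positive normalized intensities (0.00597) and converted to log2. A fold change for a gene with values at the floor depends on that floor, and no fold is given where all arrays of a group were listed at 0. No value was missing, and no pair of arrays held identical values.

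Gene names came from an older platform annotation that lists 1562 of the features and were updated through Entrez identifiers with the RefSeq gene table of assembly TAIR10.1, in which 690 of the single-gene features matched and 2 kept the annotation's name. A single gene was listed for 692 features, several genes for 870 and no entry for 1877. Features with several genes or no entry were fitted but are not named. AT2G25870 had 2 features, which were averaged on the log2 scale although they disagreed (log2 differences of 1.33 and -0.31). No genome build is stated for the array, so no coordinates are given.

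Groups were compared with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, without covariates, over 3438 rows. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 691 named genes, with 0.05 as the threshold. A count over all features, adjusted together, was added after seeing the data. The genes named are the 12 higher and 12 lower genes with the largest absolute log2 fold change past the threshold. From each gene list, up to 2 members of each direction with the largest change past the threshold were added, or the 2 with the smallest p where none passed. The 20 preset lists hold 331 genes, of which 17 were measured by a feature with a single gene name. These lists covered the lesion gene, antenna, photosystem I, photosystem II, electron transport, Calvin cycle, tetrapyrrole, isoprenoid, plastid iron-sulfur protein, iron-sulfur assembly, plastid ribosome, import, protease, light signalling, antioxidant, dark-induced, starch, photorespiration, other-tissue and housekeeping genes. Because so few members were measured, 4 further lists were put together from the gene names on the array: organelle RNA proteins, photosynthetic complexes and their assembly, fibrillins, and histone H3 with kinesin genes. They were written after the intensities of the brightest features had been seen and before any fold change was computed, and are not preset. The 5 lists with at least 3 measured members were tested against the other named genes with camera (inter-gene correlation preset at 0.01) and, as alternatives, with camera using an estimated correlation. As a further alternative fry tested each list against no change, without comparing it with other genes.

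The pipeline was tested on simulated data made from the means and spreads of the measured genes for the laf6 against WT comparison, with 200 of the 691 named genes changed. It recovered 32% of genes changed by 0.5 on the log2 scale, 52% of those changed by 1, 60% of those changed by 2 and 92% of those changed by 4, and 6 of its 124 calls were false. Among the simulated genes of the brighter part of the range, 72.7% of those changed by 1 were recovered, against 35.7% among the dimmer ones. The simulated arrays varied independently, with 1 spread per gene for both groups. The real groups differed in spread and some of their arrays resembled each other, so these rates may not hold for them. Scale factors of the simulated arrays were drawn without regard to group. The real groups differed in their medians and in the share of signal in the brightest features. The simulation therefore does not cover false calls that normalization between such groups could make.

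Alternatives were the values as deposited, median and 75th percentile scaling, cyclic loess, filters on features at or below the 25th or 50th percentile of mean log2 intensity, an offset at the 10th percentile of the positive intensities before log2, the replicate number as a block, an intensity trend with robust settings, array weights, each array left out, an exact Wilcoxon test, an adjusted p threshold of 0.01 and a minimum log2 fold change of 1. Alternatives added after seeing the data were averages or a random block over adjacent replicate numbers, chosen because arrays with adjacent numbers resembled each other (consensus correlation 0.194 within such pairs), and a fit without replicates 1 and 2. Array summaries were compared with two-sided exact permutation tests.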

Results

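The arrays measured transcript levels in dark-adapted plants of WT and of laf6, a mutant described in the labels as lacking the transporter atABC1, with 6 arrays per group. The gene is now named SUFB, a part of the machinery that assembles iron-sulfur clusters in plastids. The median deposited intensity ran from 0.218 to 0.289 over the WT arrays and from 0.178 to 0.202 over the laf6 arrays. The 20 brightest features of an array held 30.9 ± 0.755% of its summed intensity in WT and 40.5 ± 0.815% in laf6 (SD, n = 6 each). In an exact permutation test the groups differed in this share and in the median (p = 0.00216 for each, the smallest the design allows, and 0.00325 after adjustment for 3 measures). Features listed at 0 numbered 482 ± 37.3 per WT array and 597 ± 71.5 per laf6 array (exact permutation p = 0.0152, adjusted p = 0.0152). The labels do not say that the arrays came from separate plants, so p-values measure only the spread between these arrays, which may be technical.

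WT arrays resembled each other more than laf6 arrays did. The mean Spearman correlation over features was 0.924 within WT (0.907 to 0.948 over 15 pairs), 0.855 within laf6 (0.832 to 0.906 over 15 pairs) and 0.828 between the groups (0.777 to 0.869 over 36 pairs). Within a group, arrays numbered 1 and 2, 3 and 4, or 5 and 6 were closer to each other than other pairs were (mean Spearman correlation 0.939 against 0.920 in WT and 0.874 against 0.851 in laf6). It stays open whether they are repeat measurements of 1 sample, which would leave 3 samples per group and make the p-values given for 6 too small. Pearson correlations of the log2 values averaged 0.899, 0.823 and 0.808 in the same order. The first principal component, with 25.8% of the variance, separated laf6 from WT, and the second, with 12.4%, separated replicates 1 and 2 of both groups from the other arrays. Repeats of 1 sample alone would not set replicates 1 and 2 of both groups apart, so arrays of the 2 groups may also share conditions. The fits over adjacent replicate numbers joined arrays within a group only and leave such conditions out.

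The comparison asked which transcripts differ between dark-adapted laf6 and WT plants. Of 19 measured genes of photosynthesis, from the preset lists and an added list of photosynthetic complexes, 6 rose, 4 fell (PSBW, AT1G76450, NdhS and AT1G22700) and 9 did not pass. Camera found no shift of the added list in 1 direction against the other named genes (adjusted p = 0.298, and adjusted p = 0.478 with an estimated correlation). Members that moved in opposite directions can cancel in this test. PSAN, a subunit of photosystem I, rose from a normalized intensity of 4.15 ± 0.524 in WT to 13.6 ± 1.36 in laf6 (SD, n = 6 each), a log2 fold change of 1.72 ± 0.10 (SE). LHB1B2, a chlorophyll a/b-binding protein of the photosystem II antenna, rose from 19.8 ± 4.66 to 45.6 ± 4.51. The photosystem II subunit PSBW fell from 84.7 ± 10.4 to 34.3 ± 4.69, a log2 change of -1.31 ± 0.11, with 1 WT array at the top of the scale, where the signal can be understated. In all, 172 of 691 named genes passed the threshold, 71 higher and 101 lower in laf6, against 40 higher and 190 lower with the values as deposited.

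By preset list, the single antenna gene measured rose (LHB1B2, log2 fold change 1.23 ± 0.15, adjusted p = 9.25e-05), as did the single photosystem I gene measured (PSAN, adjusted p = 2.78e-07). Of the 2 photosystem II genes measured, PSBY rose by 0.73 ± 0.12 on the log2 scale (adjusted p = 0.000737) and PSBW fell (adjusted p = 6.78e-06). Of 2 Calvin cycle genes, the phosphoribulokinase gene PRK rose by 1.17 ± 0.24 (adjusted p = 0.00424) and SBPASE, listed at 0 on all 6 WT arrays and on 4 of 6 laf6 arrays, did not pass (adjusted p = 0.341). Of 2 tetrapyrrole genes, CHLM, the magnesium protoporphyrin IX methyltransferase of chlorophyll synthesis, rose by 1.28 ± 0.26 (adjusted p = 0.00328). AT1G74470, the geranylgeranyl reductase gene, did not pass (0.09 ± 0.11, adjusted p = 0.614). The single gene measured for a plastid iron-sulfur protein, AT2G04700, which encodes the catalytic subunit of ferredoxin-thioredoxin reductase, rose by 1.45 ± 0.26 (adjusted p = 0.00134). For each of these genes past the threshold, every laf6 array lay on the same side of every WT array. In these lists the count adjusted over the list alone was the same as over all named genes: 1 antenna, 1 photosystem I, 1 Calvin cycle, 1 tetrapyrrole and 1 iron-sulfur protein gene higher, and 1 photosystem II gene in each direction. PSBW depended on the scaling: its log2 change was -0.39 (adjusted p = 0.135) with median scaling and -0.36 (adjusted p = 0.136) with 75th percentile scaling, within a range of adjusted p from 4.05e-08 to 0.136 over 25 alternatives, while LHB1B2 stood at 2.08 with median scaling. As deposited, PSBY stood at 0.47, PRK at 0.76 and PSBW at -0.79, all past the threshold. With adjacent replicate numbers averaged to 3 samples per group, an alternative chosen after seeing the data, CHLM (adjusted p = 0.0657, range over alternatives 0.000892 to 0.0657) and PRK (adjusted p = 0.0721, range 0.000669 to 0.0721) missed the threshold.

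**Figure D1:**
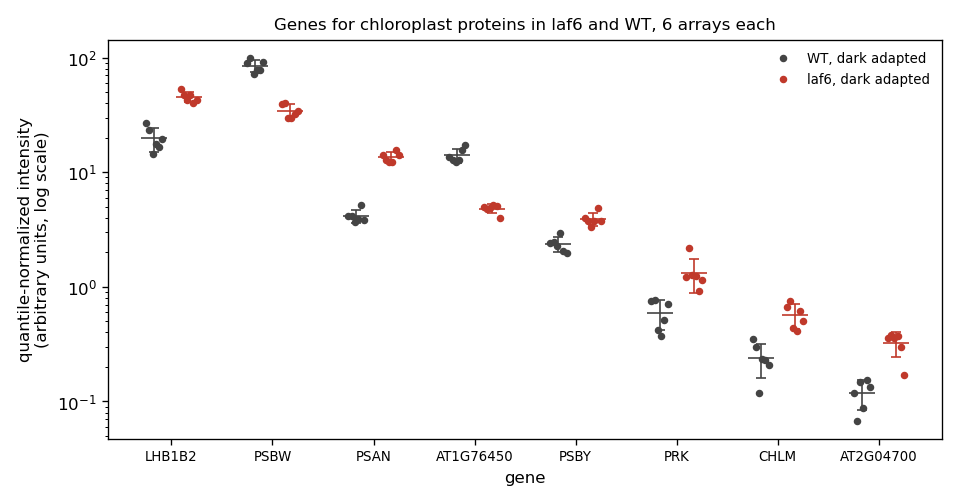
Quantile-normalized intensity (arbitrary units, log scale) of 8 genes for chloroplast proteins on each WT array (grey) and each laf6 array (red). Points are arrays, the horizontal mark is the mean of 6 arrays and the bar its SD; PSBW and AT1G76450 lie lower in laf6 and the other genes higher, and PSBW's call was lost with median and 75th percentile scaling.

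Of 6 plastid ribosomal protein genes measured, 2 rose and none fell, over all named genes and adjusted over the list alone. AT3G54210, a protein of the large subunit, rose by 0.90 ± 0.14 on the log2 scale (adjusted p = 0.000528; 0.47 as deposited, adjusted p = 0.0180), and AT5G65220, also of the large subunit, rose by 0.57 ± 0.09 (adjusted p = 0.000903). Camera found no shift of the list in 1 direction against the other named genes (median log2 difference 0.10, adjusted p = 0.298, and adjusted p = 0.478 with an estimated correlation). The fry test, which asks only whether the genes of the list moved on balance in 1 direction, gave an adjusted p = 0.0235. Its median turned below 0 under every other scaling, from -0.10 with cyclic loess to -0.44 with the values as deposited, where AT5G65220 did not pass (log2 difference 0.31, adjusted p = 0.0721, range over alternatives 0.000234 to 0.0721). AT3G52960, a peroxiredoxin gene and the single antioxidant gene measured, did not pass (1.37 ± 0.68, adjusted p = 0.177; 0.70 as deposited), nor did the dark-induced gene ETFQO (0.06 ± 1.25, adjusted p = 0.999; -0.57 to 0.69 over alternatives). The other 11 preset lists had no member with a single gene name, among them light signalling, iron-sulfur assembly and the lesion gene. SUFB itself was therefore not analysed here, and the labels could not be checked against its transcript.

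The largest increases lay mostly in weak features. AT4G05070, the bright exception, rose from 1.66 ± 0.375 to 7.29 ± 1.02 (log2 fold change 2.16 ± 0.16, adjusted p = 2.11e-06). DRT101 had a log2 fold change of 3.64 ± 0.89 (adjusted p = 0.0103) and was listed at 0 on 2 of 6 WT arrays. AT4G35980 (3.44), AT4G05030 (3.26), GLX2-1, a glyoxalase II gene (3.19), and TPP2, which encodes tripeptidyl peptidase II (3.08), were each listed at 0 on 4 of 6 WT arrays. AT1G22660 (2.89) and AT2G42490 (2.60) were at 0 on 2 WT arrays and AT4G20690 (2.37) on 1. AT3G50270 (2.36), AT1G51080 (2.17) and SIRB (1.89), which encodes the ferrochelatase of siroheme synthesis, had a signal on every array. The calls of SIRB (adjusted p = 0.0488) and GLX2-1 (adjusted p = 0.0440) were marginal: SIRB was lost under 20 of 24 alternatives, including leaving out any array but replicate 3 of laf6 (log2 1.44 to 2.27, adjusted p up to 0.0932), and GLX2-1 under 17 of 24, including leaving out any array but replicates 2 and 3 of WT (2.83 to 4.03, adjusted p up to 0.0980). AT4G20690 was lost under 9 of 24 alternatives, among them without replicate 1, 2, 3 or 6 of laf6 (adjusted p up to 0.0600 over arrays left out). AT2G42490 was lost under 5 of 24, among them without replicate 3 of laf6 (adjusted p = 0.0502). Both were lost as deposited and with array weights. Without replicates 1 and 2, an alternative chosen after seeing the data, DRT101 and TPP2 missed the threshold (highest adjusted p over alternatives 0.0601 and 0.0590), and with adjacent replicate numbers averaged AT1G22660 and AT3G50270 did (0.0869 and 0.120).

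The largest decreases included genes with a signal in WT and none listed in laf6. Among all features, 158 were listed at 0 on all 6 laf6 arrays and 147 on all 6 WT arrays, with 65 at 0 on all 12 arrays. The chromatin remodelling gene chr31 had a normalized intensity of 0.537 ± 0.149 in WT and was listed at 0 on all 6 laf6 arrays (adjusted p = 2.24e-09). AT4G38040, AT2G03140 and AT2G38950 were also listed at 0 on all 6 laf6 arrays, with WT intensities of 0.181 ± 0.0993, 0.0669 ± 0.0615 and 0.0654 ± 0.0541 and a value of 0 on 1 WT array each. AT4G03150, AT2G46190 and AT2G06040 were at 0 on 5 laf6 arrays and AT3G57630 on 4, with log2 changes of -5.55, -3.55, -3.09 and -3.83. AT2G46300 (-4.39 ± 1.13) and the chloroplast lipocalin gene CHL (-2.62 ± 0.74) were at 0 on 2 laf6 arrays. AT2G36480 fell from 1.52 ± 0.242 to 0.178 ± 0.0453 (log2 change -3.12 ± 0.17, adjusted p = 2.14e-07), and AT-HF, a gene of histidine synthesis, fell from 1.14 ± 0.0656 to 0.173 ± 0.0967 (-3.02 ± 0.45, adjusted p = 0.000504). With an offset before log2, which weighs weak signals less, the log2 fold changes of the 12 largest increases ran from 1.097 to 2.118. Those of the 8 decreases with a signal on at least 1 laf6 array ran from -3.16 to -1.13, and of the 24 only GLX2-1 missed the threshold. CHL, AT2G46300 and AT2G38950 missed it without replicates 1 and 2 (highest adjusted p over alternatives 0.1005, 0.123 and 0.163). AT2G38950 also missed it with array weights (adjusted p = 0.0683) and CHL also with adjacent replicate numbers as a random block (adjusted p = 0.0558).

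**Figure D2:**
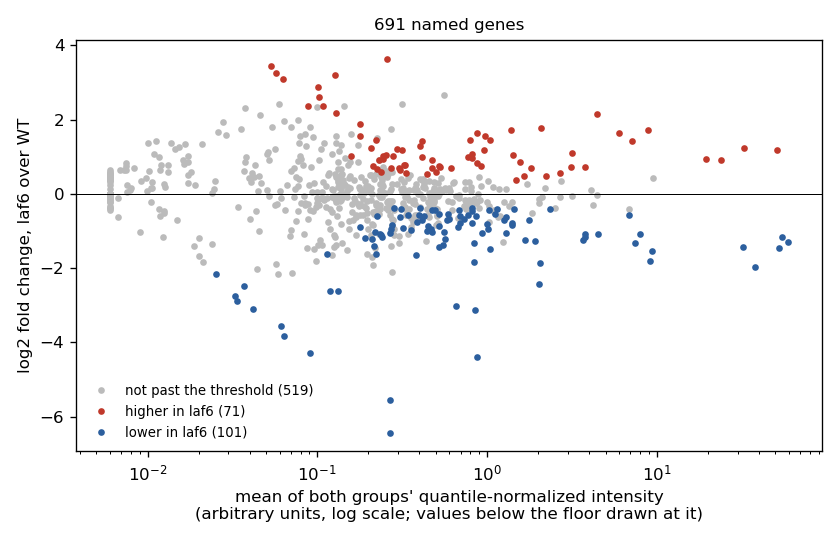
Log2 fold change of laf6 over WT against the mean quantile-normalized intensity of both groups (arbitrary units, log scale) for 691 named genes. Red points are the 71 genes higher and blue points the 101 genes lower in laf6; most of the largest changes lie at low intensity, and genes listed at 0 on all arrays of a group are drawn against the floor, which gives them no true fold.

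Among the 345 brighter named genes 56 were higher and 83 lower, and among the 346 dimmer ones 15 were higher and 18 lower, with a median standard error of 0.19 and 0.68 on the log2 scale. In 113 of 691 genes (16.4%) the laf6 and WT arrays did not overlap, against 0.216% by chance if all arrays are separate samples. That chance share does not hold if arrays with adjacent replicate numbers are repeats of the same sample, which stays open. Over all 3438 features 428 were higher and 474 lower (252 and 902 with the values as deposited), 730 of the changed ones without a single gene name. The balance of directions depended on the scaling: as deposited, where the median of all features was shifted by -0.45 on the log2 scale, 40 named genes were higher and 190 lower. With median scaling that shift was -0.10, and 71 genes were higher and 103 lower.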

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

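The tests of array scaling, of saturated spots and of splits of averaged arrays below were chosen after the results were seen. In 13 of 90 groups of 6 arrays, 1 array lay far from the other 5. In 5 of these the other 5 arrays were at the floor, where any signal stands apart. This leaves 8 of 85 groups, where chance gives about 1 in 20 for values clear of the floor. The values that follow are log2 normalized intensities, on which the floor is -7.39. For AT4G35980 the WT array of replicate 5 (-6.28) was above the floor while the other WT arrays were at it, and the laf6 array of replicate 2 (-7.39) was at the floor. A single laf6 array stood above the floor for AT2G06040 (replicate 2, -5.64), AT2G46190 (replicate 4, -4.40) and AT4G03150 (replicate 6, -2.42). For AT3G57630 it was replicate 5 (-4.65), the others being at the floor, and for AT5G19940 replicate 6 (-3.97) lay above the others. For AT4G38040 the WT array of replicate 2 (-7.39) was at the floor. Among genes with a signal on every array of the group concerned, SIRB was low in WT replicate 2 (-6.27), AT2G04700 in laf6 replicate 6 (-2.55), AT1G76450 in laf6 replicate 6 (2.004), chr31 in WT replicate 1 (-1.91), and AT1G51110 was high in laf6 replicate 5 (-2.03).

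Of the named genes 172 passed the threshold, and of all features 902. Of 100 splits of the 12 arrays into 6 and 6, 1 gave as many named genes and 1 as many features, the real split in each case. The highest of the other splits gave 2 named genes and 2 features. This argues against chance if the 12 arrays are separate samples, with 1 of 100 as the smallest share these splits could give. The splits also leave out conditions that same-numbered arrays may share. With adjacent replicate numbers averaged, in case they are repeats of 1 sample, the 10 splits into 3 and 3 are too few for a share under 0.05, with 106 named genes and 545 features for the real split and 1 of each for the highest other. Under all 4 other scalings 128 of 172 named genes (74.4%, exact binomial 95% interval 67.2 to 80.8%) kept direction and side of the threshold, 40 of 71 higher and 88 of 101 lower. For the lower genes and these scalings this argues against array scaling as the whole cause. For the higher genes, of which 40 of 71 were kept, array scaling stays open. The interval pools both directions and takes genes as separate although a scaling moves many together, so it adds little to the count. AT2G38550, named because it was the only gene to turn, went from 0.38 to -0.03 as deposited. The genotype and any difference in how the arrays of each group were grown, hybridised or scanned, on which the labels are silent, stay open.

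Of 19 measured photosynthesis genes, from the preset lists and the added list of photosynthetic complexes, 6 rose and 4 fell. Of these 10, 8 stayed past the threshold in the same direction under all 4 other scalings, 5 higher and 3 lower. The largest move by a scaling, 0.94, was that of PSBW, which is not among these 8, and the smallest change, 0.69, was that of AT1G22700. These 2 values therefore do not show that the scalings could have turned any of the 8. The calls of the 8 held under each scaling tried, which by itself cannot decide on array scaling as the whole cause. For the other 2 array scaling cannot be told apart. PSBW went from -1.31 ± 0.11 (SE) to -0.39 ± 0.17 with median scaling and PIFI from 0.74 to 0.30 (limma adjusted p = 0.197) as deposited. These changes were too small against their spread to pass, and neither gene turned. Of the 120 array values of the 10 genes, 0.833% stood at the top of the scale. This cannot decide on saturated spots, since it is not known whether saturated values would stand there. The share is also pooled over bright and dim genes. Spill-over from neighbouring spots cannot be told apart: features numbered directly before or after a member had a median change of 0.10 in its direction (95% bootstrap interval -1.15 to 0.50, 13 neighbours), below 0.56, 50% of the members' median absolute change, but nothing says that the numbers follow the layout of the array, and a difference between the genotypes also stays open.

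Of the 24 largest changes, 20 lay in the dimmer part of the named genes, 11 higher and 9 lower. Noise near the floor as the cause would leave the direction to chance in other arrays. Of 37 dim genes with an unadjusted limma p under 0.05 in replicates 1 to 3, 86.5% went the same way in replicates 4 to 6 (exact binomial 95% interval 71.2 to 95.5%), against 94.1% of 153 brighter genes. Of 49 found in replicates 4 to 6, 83.7% went the same way in replicates 1 to 3. The median size went from 2.40 to 1.098 on the log2 scale for the former set and from 1.54 to 1.43 for the latter, so how far noise shaped the sizes stays open. Arrays numbered 3 and 4, possibly repeats of 1 sample, fell on different sides of this split, and the interval takes genes on the same arrays as separate. The agreement thus argues against random noise only if the arrays are separate samples. It does not bear on a group difference near the floor, which would repeat.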

How the results depend on the processing

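The fits over adjacent replicate numbers and without replicates 1 and 2 were chosen after seeing the data. Of the 44 genes picked by size of change or from the lists, 40 passed the threshold in the main fit. Of these 40, 21 kept their direction and side under every alternative that gave them a value, 19 lost the call under at least 1 and none reversed. The rank test and stricter thresholds were run for counts only. As most were picked for large changes, these shares do not describe all 172 genes past the threshold. The count of 172 genes ran from 149 to 170 with each array left out, and all features from 812 to 895. As deposited, 40 genes were higher and 190 lower, and 252 and 902 of all features, with a common shift of -0.45 on the log2 scale. Median scaling of the same values brought the shift to -0.10 and gave 71 and 103 genes and 416 and 476 features, so the shift accounts for most of the difference. Requiring an adjusted p under 0.01 left 66 lower genes and 310 lower features, and requiring a log2 change of 1 left 91 genes, 38 higher and 53 lower, and 450 features, 257 higher and 193 lower; both only tighten the threshold. With adjacent replicate numbers averaged there were 106 genes, 57 of them lower, and 545 features, 256 of them lower, with 3 samples per group in place of 6. All other counts of genes and features stayed within 1.5 times. Same-numbered arrays deviated together with correlations of 0.10 to 0.18, all above the highest between different numbers (0.0718). The lowest was just under the limit of 0.1 set for pairing (0.0966), so the numbers were not taken to pair the arrays. Over the brighter features the same-numbered correlations were 0.178 to 0.399, against at most 0.164 between different numbers. There all 12 arrays correlated best with their own number, as they did over all features. This points to conditions shared by same-numbered arrays, which the labels do not name. The main fit and the splits of the arrays leave such shared conditions out. With the replicate block 160 genes passed, 148 of them among the 172. Of the genes named here, GLX2-1 (limma adjusted p = 0.0902), AT3G44050 (0.0804), SIRB (0.0772), AT5G55580 (0.0723) and AT4G20690 (0.0662) lost the call with it. Camera called 0 of 5 lists under each alternative it was run with (of 4 with the 50th percentile filter). It was not run with the average or the random block over adjacent replicate numbers. The fry test, which does not compare a list with other genes, called 2 for a shift in 1 direction. These were plastid ribosomal proteins (adjusted p = 0.0235) and histone H3 and kinesin genes (adjusted p = 0.0402), and the cause was not tested. SUFB had no value under any setting, and the fibrillin list was too small to test with the 50th percentile filter. Array signal near the floor limits the dim genes.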

Other observations

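The test of the added lists was chosen after seeing the gene names on the array. Among 17 genes of photosynthetic complexes and their assembly, 5 rose, 4 fell and 8 did not pass; adjusted over the list alone, 6 rose and 4 fell. AT1G76450, which encodes a PsbP-domain protein of the thylakoid lumen, fell from 14.1 ± 1.96 to 4.81 ± 0.424 (SD, n = 6 each), a log2 change of -1.54 ± 0.10 (SE, limma adjusted p = 9.02e-07). Camera found no shift of the list in 1 direction against the other named genes (adjusted p = 0.298, and adjusted p = 0.478 with an estimated correlation). Neither did fry against no change (adjusted p = 0.0810). Both can miss changes in opposite directions. Without regard to direction fry gave an adjusted p of 1.21e-12, and 6.82e-14 for the organelle RNA proteins below. That test does not compare a list with other genes.

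Among 26 genes for organelle RNA proteins of the pentatricopeptide repeat and mTERF families, 3 rose, 4 fell and 19 did not pass, with the same counts adjusted over the list alone. AT3G26630, a pentatricopeptide repeat gene, rose from 16.6 ± 1.05 to 31.2 ± 0.908 (SD, n = 6 each), a log2 fold change of 0.91 ± 0.06 (limma adjusted p = 9.68e-07), and 1.62 with median scaling. AT3G49740, of the same family, fell by 1.61 on the log2 scale (limma adjusted p = 0.00120), by 0.999 with an offset before log2, and missed the threshold with adjacent replicate numbers averaged (adjusted p = 0.0524). The mTERF genes AT5G55580 (0.76 ± 0.24, limma adjusted p = 0.0382) and AT1G62150 (-0.59 ± 0.18, limma adjusted p = 0.0331) were marginal, losing the call under 13 and 11 of 25 alternatives and each when any of 8 single arrays was left out (0.66 to 0.92 and -0.69 to -0.51). As deposited, AT5G55580 stood at 0.35 (adjusted p = 0.339, range over alternatives 0.00813 to 0.339) and AT1G62150 at -1.04 (adjusted p = 0.00194). Camera found no shift of the list in 1 direction against the other named genes (adjusted p = 0.366, and adjusted p = 0.576 with an estimated correlation). Of 8 histone H3 and kinesin genes, 2 fell: the histone H3 gene AT1G13370 by 1.26 on the log2 scale (limma adjusted p = 0.000481) and the kinesin gene AT3G44050 by 0.45 (limma adjusted p = 0.0257). AT3G44050 lost its call under 5 of 25 alternatives, among them cyclic loess and leaving out replicate 3 or 5 of WT (log2 -0.35 at the least, adjusted p up to 0.0549 over arrays left out and 0.125 over all alternatives). It stood at -0.89 as deposited. That list had a camera adjusted p of 0.594, and adjusted p = 0.625 with an estimated correlation. None of 5 fibrillin genes passed (camera adjusted p = 0.825, and adjusted p = 0.826 with an estimated correlation), AT1G51110 standing at 0.78 ± 0.43 (limma adjusted p = 0.229) and AT5G19940 at -1.35 ± 0.79 (limma adjusted p = 0.260). AT1G51110 ran from 0.44 to 1.11 over arrays left out, passing only without replicate 5 of WT (adjusted p = 0.0486), and stood at 0.32 as deposited. AT5G19940 stood at -0.43 with an offset before log2.

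A hypothesis that position on the array shaped the changes was tested by asking whether features with neighbouring numbers changed together. The rank correlation of log2 fold changes between features whose numbers differ by 1 was 0.0307 over 2558 pairs, inside the range of shuffled numbers (-0.04 to 0.04). Of the 24 distances between numbers examined, a distance of 12 gave 0.0924 (permutation p = 0.001, the smallest the shuffles can give, adjusted p = 0.024), outside its shuffled range (-0.04 to 0.03), and distances of 6 and 18 gave 0.0462 and 0.0479 (permutation p = 0.01 each, adjusted p = 0.08). Features 12 numbers apart thus changed together slightly more than chance gives. As the layout of the numbers is not given in the sources used here, effects of position stay open.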
